A study of Arabidopsis thaliana with 19 samples.

How the data were processed

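Nuclei of Arabidopsis thaliana leaf cells were isolated by INTACT, in which a nuclear envelope tag is biotinylated in chosen cells and the nuclei are pulled out on beads. Per the labels, 2 transgenic lines in the Col-0 accession carried the tag: GAS1p:NTF/ACT2p:BirA for vasculature and FDHp:NTF/ACT2p:BirA for epidermis. Plants grew for 14 short days (8 h light at 22 °C, 16 h darkness at 20 °C) and then had 3 more short days or 3 long days (16 h light, 8 h darkness). Chromatin accessibility was measured by ATAC-seq on 50000 nuclei per library, with 2 libraries in each of 4 groups (8 libraries). RNA-seq used nuclear RNA of 100000 nuclei per library, with 3 libraries per group and 2 in short-day vasculature (11 libraries). Cell type and transgenic line went together in every library. The hour of harvest, and whether replicates came from separate plants, are not given in the sources used here.

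The authors' RNA table held a signal per gene and library, and per the labels HISAT2 and DESeq2 were the tools and TAIR10 the build. Each value was a whole number of reads divided by 1 size factor per library: 100% of the values were whole multiples of the library's step within 1e-06, and the largest deviation was 1.6e-10. Whole reads were therefore recovered from it. The read counter and the filter that left 19858 genes are not given in the sources used here. The authors' peak lists, 1 per group over both of its libraries, gave for each peak a ratio, the fold of its height over the local background. The deposited lists also gave a −log10 of the q value per peak. The peak caller is not given in the sources used here, and the layout of the columns was read from the values. The deposited read positions, aligned with Bowtie2 per the labels, carried a mapping quality score of 11 to 42 per read end. Plastid and mitochondrial reads and reads at identical positions were still in them, and read lengths went up to 178 bp. The number of columns left unused was 0.

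RNA was tested with limma 3.58.1 in R 4.3.3 on log2 of the normalized count plus 1, for genes with a mean of at least 10 over the libraries, with an intensity trend and 1 coefficient per group. Peaks of the 4 lists that shared at least 1 bp were merged into consensus peaks on the 5 nuclear chromosomes. Read ends overlapping each were counted and tested with edgeR 4.0.16 (quasi-likelihood, TMM scaling, low-count filter of the package). In both assays the fit held all groups, so that groups of 2 or 3 libraries shared 1 estimate of the spread. Replicates 1 and 2 of short-day epidermis agreed less than those of the other groups. Their correlation was 0.908 in RNA (0.952 to 0.956 elsewhere) and 0.946 in ATAC (0.965 to 0.975 elsewhere). Standard errors and p values of contrasts with this group may therefore be too small. The contrasts were vasculature minus epidermis as the mean over photoperiods, long minus short days in each cell type, and the difference between these long-day effects. P values were adjusted by Benjamini-Hochberg over all genes or peaks of a contrast, and an adjusted p under 0.05 was called. All tests were two-sided. Counting and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

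The contrasts, tests, gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. The permutation test of FT was not among these tests. There were 17 gene lists: phloem, xylem and cambium, epidermis and cuticle, stomatal lineage and guard cells, trichome, mesophyll and photosynthesis, circadian clock, photoperiod and flowering, light signalling, flavonoid and anthocyanin, sugar starvation, starch and sugar transport, early wound and touch response, salicylic acid defence, glucosinolate, cell cycle, and genes related to the transgenes. Each list was tested with camera of limma at a preset correlation of 0.01 between genes, with an estimated correlation and with fry, adjusted over the lists of a contrast. Counts of called members are given over all genes tested and adjusted over the list alone. FDH is in both the epidermis and the transgene list.

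Named genes followed 3 parts of a rule: 16 anchor genes given in every RNA comparison, the 3 members of each list with the smallest adjusted p, and the 8 genes with the largest change in each direction. Genes of that last part had to be called, reach a mean of 50 in the higher group and show no overlap between groups. Named peaks lay within 3000 bp of 10 chosen genes (8000 bp for FT), or were the 5 largest changes in each direction, called, with a mean count of 50 and no overlap. For the difference between long-day effects, genes and peaks needed no overlap between long and short days in at least 1 cell type. Because the gene annotation used here gives no strand, promoter windows were replaced by the gene and 1000 bp on both sides, with 500 and 2000 bp as alternatives, and of several peaks the one with the most reads stood for the gene. For the same reason, peak positions were classed by gene edges and not by promoter, exon or untranslated region. Motif tests, and their window alternative, were not run because no genome sequence was used here. Positions are on TAIR10, counted from 1.

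Recovered RNA reads ranged from 729741 to 8227810 per library, and ATAC reads from 8804056 to 16952026. A count of 0 was read as allowing up to 3 reads in the group, and this floor covers counting error only, since reads without molecular identifiers are not independent molecules. On simulated data with libraries of these sizes, the RNA fit recovered 49.5% of 2-fold and 98.0% of 4-fold differences between cell types. It recovered 13% of 2-fold and 83% of 4-fold long-day effects in epidermis, 9.62% and 75.8% in vasculature, and 0% and 23.8% of differences between them, so that many 2-fold changes would not be called. The ATAC fit, also tested on simulated data, recovered 70.1% to 94.1% of 2-fold differences in the first 3 contrasts and 41% in the difference between long-day effects. False calls made up 1.03% to 5.85% of the simulated calls. Within an assay all genes or peaks and all libraries were simulated with the same spread. The real libraries agreed unevenly within groups, so the recovered and false shares may not carry over to them.

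Alternatives for RNA were pseudocounts of 0.5 and 5, no filter or a mean of 50, quantile normalization, equal nuclear totals without organelle genes, edgeR and DESeq2 1.42.0 on recovered reads, and fits of only the 2 groups of a long-day contrast. For ATAC they were DESeq2 size factors, library totals, a loess offset (span 0.3), DESeq2, no filter, peaks of 2 or more lists, the top part of each list by score, identical positions counted once, and 5 prime ends. Both assays were also run with the replicate number as a block, with an absolute log2 change of at least 1, and without each library in turn. Where a group then kept 1 library, that library was assumed to vary like the other groups. Chosen after seeing the data were limma voom weights, leaving out the 3 shallow RNA libraries, a flow cell term, the first flow cell alone, a mapping quality of at least 30, and a crossed pairing of the epidermis libraries.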

Results

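Chromatin accessibility and nuclear RNA were measured in nuclei of leaf vasculature and leaf epidermis of Arabidopsis under long and short days. Vascular nuclei were tagged under the GAS1 promoter and epidermal nuclei under the FDH promoter, in separate transgenic lines. ATAC-seq had 2 libraries in each of 4 groups, 8 in all. RNA-seq had 11 libraries, 3 per group except for 2 in short-day vasculature. The questions were which genes and accessible regions separate the cell types, and which respond to 3 long days in each of them. The labels give no hour of harvest, so the length of the day and the hour of sampling were not separated.

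Recovered RNA reads ranged from 4485950 to 8227810 in 8 libraries and were lower in the third library of long-day epidermis (1396200), short-day epidermis (1666920) and long-day vasculature (729741). Photosynthesis genes of the mesophyll list took 2.98% to 5.28% of the reads of each RNA library, and the 10 most abundant genes took 4.08% to 6.30%. Phloem and epidermis markers were both read in both cell types. SUC2 (AT1G22710), a companion cell sucrose transporter, had 348 ± 53.8 normalized counts in long-day epidermis and 718 ± 125 in long-day vasculature (SD, n = 3). FDH (AT2G26250), an epidermal fatty acid elongase, had 1740 and 1738 in the same groups. ATAC libraries held 8804056 to 16952026 reads. Peaks took 55.8% and 56.7% of nuclear reads in long-day epidermis, 48.9% and 47.6% in short-day epidermis, 47.9% and 49.8% in long-day vasculature, and 38.6% and 38% in short-day vasculature. Plastid reads made up 5.71% to 7.12% of epidermal and 9.93% to 12.2% of vascular ATAC libraries.

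The first RNA comparison asked which genes differ between vascular and epidermal nuclei, as the mean over both photoperiods (5 against 6 libraries). Of 15 phloem genes 7 were higher in vasculature and 8 were not called, and the list did not pass with an estimated correlation (adjusted p = 0.0932). SUC2 was 1.24 ± 0.147 higher (log2 ± SE, adjusted p = 0.00071), the phloem regulator APL 1.96 ± 0.310 (adjusted p = 0.00686) and the sucrose exporter SWEET11 1.15 ± 0.183 (adjusted p = 0.00699). Of 27 epidermis and cuticle genes 5 were lower and 22 not called, and the list did not pass with an estimated correlation (adjusted p = 0.115). CER1 was at −1.80 ± 0.228 (adjusted p = 0.00112), HTH at −1.18 ± 0.200 and LACS1 at −0.92 ± 0.156 (adjusted p = 0.00934 for both). RANGAP1 (AT3G63130), a segment of which is in the nuclear tag of both lines, was lower by −1.74 ± 0.171 (adjusted p = 0.000146), with 647 ± 127 normalized counts in long-day epidermis and 158 ± 28.2 in long-day vasculature (SD, n = 3).

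Of 15830 genes tested, 145 differed between the cell types, 76 higher and 69 lower in vasculature. An unadjusted p under 0.05 was reached by 1992 genes. The largest increases without overlap between the cell types were the seed protein genes CRU3 (4.24 ± 0.75), ATECP31 (3.56 ± 0.604) and PER1 (2.93 ± 0.566), followed by AT3G13404, AT2G28810, AT4G24450, AT5G54660 and AT4G16008 at 2.73 to 2.24. CRU3 had 76.5 normalized counts in long-day vasculature and 8.63 in long-day epidermis. The largest decreases were AT1G06090 (−5.15 ± 0.551), AT3G03130, CXE18, AT4G22505 (−2.02 ± 0.195), AT2G38995 and AT1G11670. The trichome regulator GL2 was lower by −1.11 ± 0.246, the myrosinase genes TGG2 and TGG1 by −1.01 ± 0.192 and −0.87 ± 0.188, and the cyclin CYCD3;1 by −1.76 ± 0.363. Among the other genes chosen beforehand, FDH (0.24, adjusted p = 0.567), the epidermal regulator ATML1 (−0.04, adjusted p = 0.969) and ACT2 (−0.04, adjusted p = 0.949) were not called. The same held for GI, FKF1, CCA1, LHY, TOC1, SOC1, CO, RBCS1A and CA1, whose adjusted p values lay between 0.494 and 0.959. FT and the guard cell gene MYB60 were below the count filter. EIL1, looked up after its accessibility had been seen, was 1.71 ± 0.218 higher (adjusted p = 0.00112), and the ATAC reads at this gene are incomplete in the epidermis line.

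Adjusted over the list alone, 9 phloem genes were higher and 6 epidermis and cuticle genes lower. The camera test at a preset correlation gave an adjusted p of 2.24e-13 for phloem (0.0932 with an estimated correlation) and of 1.25e-06 for epidermis (0.115 with an estimated correlation). Trichome genes had 1 of 5 lower (adjusted p = 0.00664, and 0.104 with an estimated correlation), cell cycle genes 1 of 12 (0.000911, and 0.104) and stomatal genes 0 of 7 (0.0469, and 0.3). The wound and touch list (median −0.48, camera adjusted p = 1.44e-05, and 0.235 with an estimated correlation) had 0 of 18 called and 5 lower when adjusted over the list alone. Starvation (median 0.40, adjusted p = 0.000172) and light signalling genes (median 0.36, adjusted p = 0.00113) also passed the camera test at the preset correlation, each with an adjusted p of 0.115 with an estimated correlation and 0 members called. The other lists did not pass it: xylem and cambium (8 tested), mesophyll (23), clock (30), flowering (27), flavonoid (13), starch (9, median 0.17 with a camera direction of down) and salicylic acid (5) had 0 members called, glucosinolate 2 of 17 lower and the transgene list 1 of 3 lower. Of the 25 named calls, those of SUC2, RANGAP1, CER1, AT2G28810, AT4G24450, AT1G06090, AT4G22505 and AT1G11670 held without any 1 library. The other 17, APL, SWEET11, HTH, LACS1, GL2, TGG1, TGG2, CYCD3;1 and CRU3 among them, did not, and 16 were lost without the first library of short-day vasculature. Called genes numbered 567 without replicate 2 of short-day epidermis, 15 and 43 without replicates 1 and 2 of short-day vasculature, 76 without replicate 1 of long-day epidermis, and 86 and 90 without replicates 1 and 2 of long-day vasculature.

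**Figure D1:**
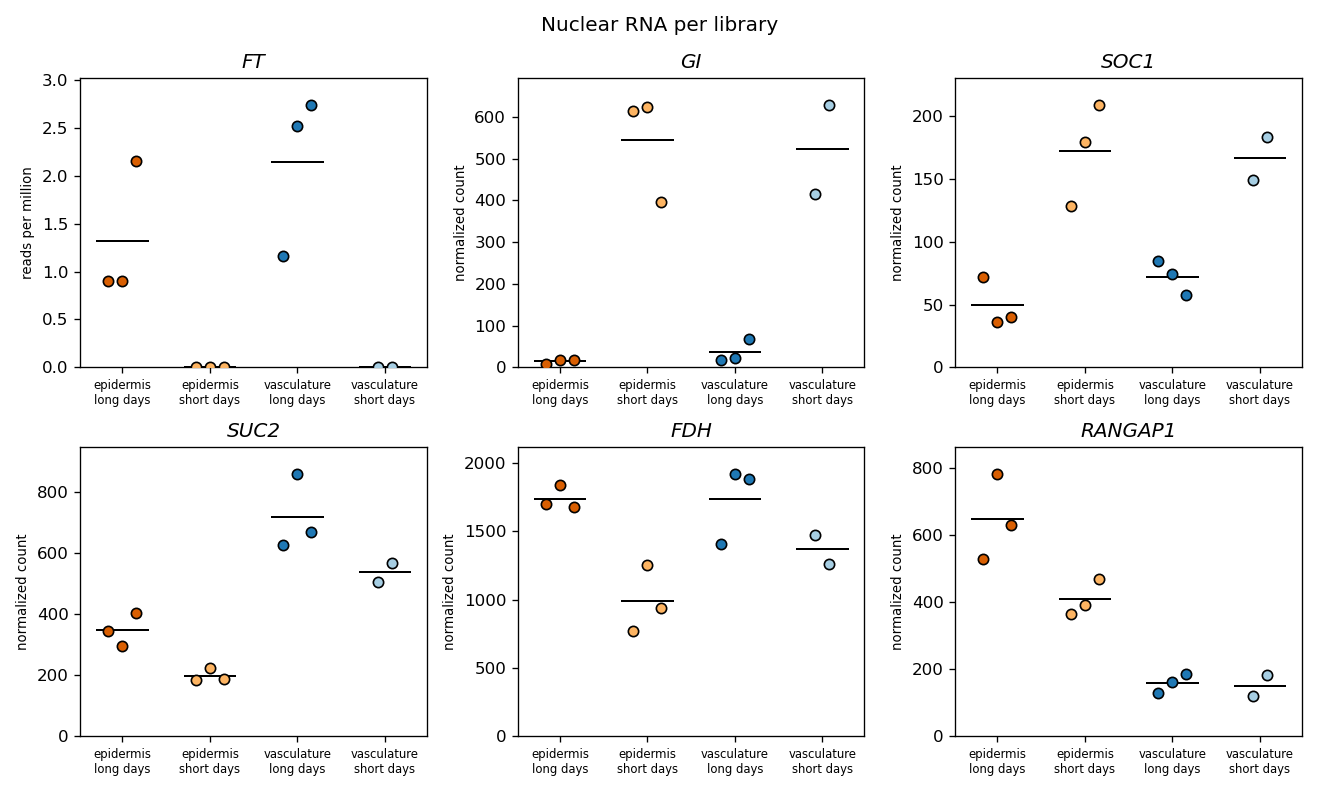
Nuclear RNA of FT (CPM, reads scaled to library size) and of GI, SOC1, SUC2, FDH and RANGAP1 (normalized count), with 1 point per library and a line at the group mean. FT had 0 reads in the 5 short-day libraries, and GI fell in both cell types in long days.

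The second comparison asked which nuclear transcripts respond to 3 long days in the epidermis (3 against 3 libraries). The clock gene PRR7 fell by 5.37 ± 0.242 on the log2 scale (adjusted p = 1.18e-09), from 3642 to 90.6 normalized counts, and the clock gene RVE2 rose by 4.87 ± 0.201 (adjusted p = 5.73e-10). GI (AT1G22770) fell by 5.22 ± 0.431 (adjusted p = 7.45e-07), from 545 to 14.2. The flowering integrator SOC1 (AT2G45660) fell by 1.82 ± 0.308 (adjusted p = 0.000882), from 172 to 49.3. Of 13 flavonoid genes 12 rose, with CHS 5.25 ± 0.859 higher (adjusted p = 0.000681). The light-harvesting gene LHCB1.1 fell by 6.0 ± 0.298 (adjusted p = 3.66e-09), from 8722 to 137, and the starvation gene DIN6 by 5.25 ± 0.441 (adjusted p = 8.91e-07), from 3643 to 79.7.

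Long days changed 1650 of 15830 epidermal genes, 714 higher and 936 lower. Scaled to equal nuclear totals, 1055 were higher and 718 lower. Of 30 clock genes, 5 rose and 14 fell. They included LHY (4.15 ± 0.976, adjusted p = 0.0105), FKF1 (−1.92 ± 0.276) and TOC1 (−0.79 ± 0.201, adjusted p = 0.0174), while CCA1 (−0.12, adjusted p = 0.906) was not called. Flavonoid genes that rose included DFR (2.95 ± 0.302), UGT78D2 (2.60 ± 0.370) and TT19 (1.80 ± 0.239). Of 23 mesophyll and photosynthesis genes, 8 rose, CA1 (0.85 ± 0.234) among them, and 10 fell, LHCB2.2 (−4.00 ± 0.226) and LHCB3 (−3.48 ± 0.204) among them. RBCS1A (0.54, adjusted p = 0.31) was not called. Of 18 wound and touch genes, 13 fell, such as JAZ7 (−2.64 ± 0.355), TCH4 (−2.06 ± 0.348) and WRKY33 (−1.48 ± 0.260). Of 8 starvation genes, 5 fell, such as TPS11 (−2.11 ± 0.236) and TPS8 (−1.37 ± 0.229). Of 9 starch and sugar transport genes, BAM3 (1.61 ± 0.189) was among 5 that rose, and STP13 (−2.96 ± 0.242) and STP1 (−2.50 ± 0.379) were the 2 that fell.

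Of 27 epidermis and cuticle genes, 6 rose, such as KCS6 (1.17 ± 0.184), ANL2 (0.85 ± 0.180) and FDH (0.84 ± 0.204, adjusted p = 0.0127), and ATML1 (0.46, adjusted p = 0.405) was not called. Of 15 phloem genes, AAP2 (2.07 ± 0.369), SWEET11 (1.18 ± 0.245) and SUC2 (0.80 ± 0.196, adjusted p = 0.014) rose. Among 27 flowering genes, NF-YB2 rose (1.15 ± 0.281), SOC1 and FLC (−0.89 ± 0.235) fell, and CO (0.43, adjusted p = 0.591) was not called. In light signalling, HYH (3.01 ± 0.380) was 1 of 2 genes of 10 that rose, and PIF4 (−3.84 ± 0.199) and PIF5 (−2.00 ± 0.193) were among 3 that fell. Of 7 stomatal genes KAT1 fell (−1.09 ± 0.256). Of 17 glucosinolate genes MYB28 rose (1.27 ± 0.238) and MAM1 (−1.06 ± 0.186) and SUR1 (−0.74 ± 0.209) fell, and of 5 salicylic acid genes WRKY70 rose (1.18 ± 0.344). No xylem (8 tested), trichome (5) or cell cycle (12) genes were called, and of the 3 transgene genes FDH was called and RANGAP1 (0.65, adjusted p = 0.0842) and ACT2 (0.55, adjusted p = 0.155) were not. The largest increases without overlap also included cPT4 (4.49 ± 0.626), AMT1;2 (4.04 ± 0.276), AT5G54240, PAP2, AT2G15020 and GASA1 (3.59 ± 0.376). The largest decreases also included AT3G55580 (−5.71) and WAKL10 (−5.45). TPS03, with 240 normalized counts in short days, and GolS3, with 59.0, had 0.219 and 0.183 in long days. CIPK20 and AT1G30730 had 90.9 and 67.9 in short days and 0 in long days, where 3 reads over the group would be 0.220 CPM. With 3 against 3 libraries, chance alone parts the groups in 10% of genes.

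Adjusted over the list alone, 6 clock genes rose and 16 fell, 12 flavonoid genes rose, 8 mesophyll genes rose and 13 fell, 14 wound genes fell, 15 epidermis and 5 phloem genes rose and 3 transgene genes rose, and 2 glucosinolate genes rose and 7 fell. The flavonoid list passed the camera test (median 2.95, adjusted p = 2.48e-12) and did so with an estimated correlation (adjusted p = 0.0388). With an estimated correlation the other calls were lost: wound (adjusted p = 1.59e-10, then 0.0990), epidermis (8.40e-09, then 0.0855), starvation (2.21e-06, then 0.0855), clock (0.000121, then 0.0855), mesophyll (0.000125, then 0.442), phloem (0.000565, then 0.214), transgene (0.0143, then 0.0990) and starch (0.0302, then 0.0990). Flowering, light signalling, salicylic acid, glucosinolate, cell cycle, xylem, stomatal and trichome lists did not pass at the preset correlation. Of the 52 named calls, 41 held without any 1 library. The calls of SUC2, FDH, LHY, TOC1, CA1, NF-YB2, FLC, WRKY70, SUR1, WAKL10 and AT1G30730 did not, and 8 of them were lost without replicate 1 of short-day epidermis.

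FT (AT1G65480), the mobile flowering signal, was too low for the fit and was read in long days alone. Long-day libraries held 2 to 14 reads each, 14 in all in epidermis (1.03 CPM) and 23 in vasculature (1.87 CPM). All 5 short-day libraries held 0 reads, which allows up to 0.246 CPM in epidermis and 0.186 in vasculature (3 reads over the group). The long-day values were thus 4.19 times the short-day limit in epidermis and 10.1 times in vasculature. These ratios are not strict lower bounds, because the long-day reads carry counting error too. The limit also rises with fewer libraries, to 0.365 or 0.378 CPM for 1 library of short-day vasculature. Between the 6 long-day and 5 short-day libraries of both cell types together, an exact two-sided permutation test over 462 splits gave p = 0.00649. This test was not among those fixed beforehand, and its splits did not keep the cell types apart. Neither cell type was tested alone. Whether FT differed between the cell types was not tested.

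The same question in vasculature (3 against 2 libraries) gave these values. PRR7 fell by 5.34 ± 0.271 (adjusted p = 1.19e-08), from 3628 to 88.6 normalized counts, PRR5 by 3.49 ± 0.292 and GI by 4.01 ± 0.482 (adjusted p = 5.24e-05), and RVE2 rose by 3.19 ± 0.224 (adjusted p = 1.65e-07). Of 13 flavonoid genes 9 rose, with TT7 6.47 ± 0.611 higher (adjusted p = 4.26e-06). SOC1 fell by 1.2 ± 0.344 (adjusted p = 0.0445), from 166 to 72.2, a call that was lost without any 1 of the 5 vascular libraries. CBF3, a cold response regulator, fell by 6.07 ± 1.07 (adjusted p = 0.00172), from 178.1 to 3.73. JAZ7 rose by 2.29 ± 0.397 (adjusted p = 0.00155), whereas it fell in epidermis.

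Long days changed 1125 of 15830 vascular genes, 564 higher and 561 lower. With equal nuclear totals 695 were higher and 486 lower. Of 30 clock genes, 4 rose and 13 fell, FKF1 (−2.90 ± 0.308) among them, while LHY (2.48, adjusted p = 0.216), TOC1 (−0.72, adjusted p = 0.0659) and CCA1 (0.23, adjusted p = 0.832) were not called. Flavonoid genes that rose included DFR (4.11 ± 0.338), CHS (4.16 ± 0.961), LDOX (3.85 ± 0.585), PAP2 (4.18 ± 0.916) and TT19 (3.51 ± 0.267). Of 23 mesophyll genes, 10 fell, such as LHCB1.1 (−5.13 ± 0.333), LHCB2.2 (−3.84 ± 0.253) and LHCB3 (−3.28 ± 0.228), and RBCS1A (0.52, adjusted p = 0.426) and CA1 (−0.03, adjusted p = 0.967) were not called. Of 18 wound and touch genes, 4 rose, ZAT12 (1.86 ± 0.363) and JAZ7 among them, and 3 fell, CBF3 among them. Of 10 light signalling genes, 1 rose and 4 fell, PIF4 (−3.22 ± 0.222), PIF5 (−1.73 ± 0.216) and ATHB-2 (−2.05 ± 0.413) among them. Among 27 flowering genes TEM2 rose (1.49 ± 0.420), SOC1 and TOE2 (−0.81 ± 0.212) fell, and CO (0.06, adjusted p = 0.962) was not called.

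Of the other lists, 1 phloem gene of 15 rose, AAP2 (1.45 ± 0.412), while SUC2 (0.41, adjusted p = 0.336) and SWEET11 (0.79, adjusted p = 0.0971) were not called. CER3 (1.07 ± 0.220) and KCS6 (0.89 ± 0.206) were the 2 of 27 epidermis genes that rose, and FDH (0.33, adjusted p = 0.465), ATML1 (0.11, adjusted p = 0.901), RANGAP1 (0.08, adjusted p = 0.899) and ACT2 (0.81, adjusted p = 0.07) were not called. TPS8 (1.27 ± 0.256) was the 1 starvation gene of 8 that rose, BAM3 (1.37 ± 0.211) rose and STP13 (−2.93 ± 0.271) fell among 9 starch genes, WRKY70 (2.1 ± 0.385) rose among 5 salicylic acid genes, and MCM4 (−3.52 ± 0.800) and MCM5 (−1.41 ± 0.359) fell among 12 cell cycle genes. No xylem, stomatal, trichome or glucosinolate genes were called. The largest changes without overlap, which chance gives in 20% of genes with 3 against 2 libraries, also included rises of AT5G59670 (5.11), AT5G42530 (4.13) and AT1G34060 (3.82) and a fall of AT1G20030 (−7.11). TPS03, GolS3 and AT1G53100 had 0.822, 1.76 and 0.411 normalized counts in long days and 172, 128 and 57.0 in short days. CIPK20 had 0 in long days, where 3 reads over the group would be 0.244 CPM, and 182 in short days.

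In vasculature the flavonoid list passed the camera test (median 3.43, adjusted p = 3.72e-12) and passed with an estimated correlation (adjusted p = 0.0404). With an estimated correlation the other calls were lost: mesophyll (adjusted p = 1.14e-06, then 0.359), clock (3.15e-05, then 0.0802), epidermis (0.0323, then 0.454) and salicylic acid (0.0323, then 0.359). The remaining lists did not pass at the preset correlation, with wound, phloem, starvation, starch, xylem and glucosinolate among them. Adjusted over the list alone, 7 clock genes rose and 16 fell, 12 flavonoid genes rose and 1 fell, 3 mesophyll genes rose and 11 fell, 5 wound genes rose and 3 fell, and 4 starch genes rose and 2 fell. Of the 40 named calls, 25 held without any 1 library. Those of SOC1, AAP2, CER3, KCS6, TOE2, TEM2, ATHB-2, TPS8, ZAT12, WRKY70, MCM4, MCM5, PAP2, CHS and GolS3 did not, and 12 of them were lost without replicate 2 of short-day vasculature. The number of called genes was 460 without replicate 1 and 425 without replicate 2 of short-day vasculature. Of the genes called in epidermis and vasculature, 659 were shared, 643 of them in the same direction (272 higher and 371 lower, against 25.4 and 33.2 by independent lists) and 16 in opposite directions. Across genes, which are not independent replicates, the long-day effects had a Spearman rho of 0.399.

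**Figure D2:**
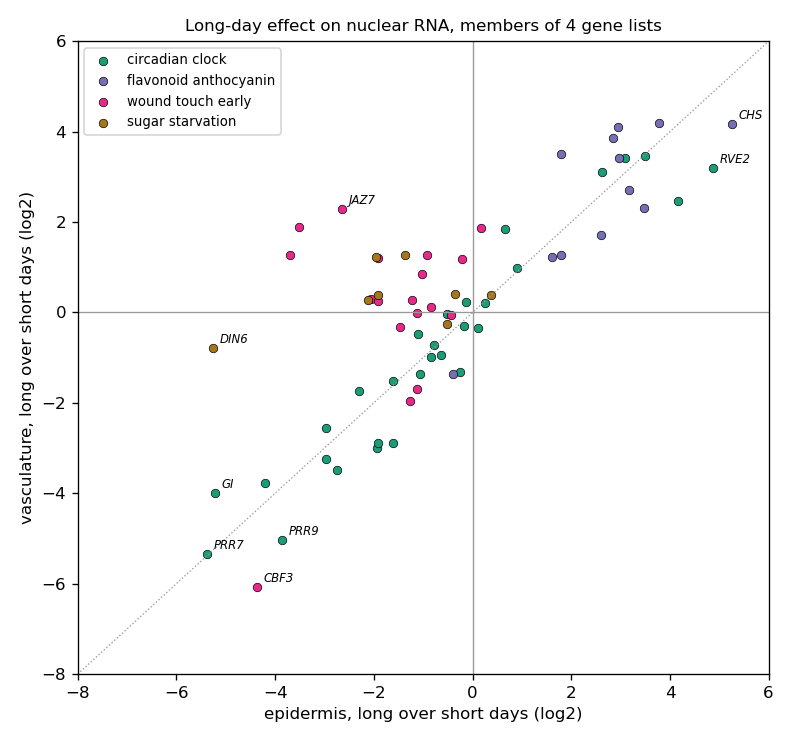
Long-day effect (log2) on nuclear RNA in epidermis (horizontal) and vasculature (vertical) for members of 4 gene lists, 1 point per gene. PRR7 (−5.37 and −5.34) lay near the diagonal, and JAZ7 (−2.64 and 2.29) far from it.

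The fourth comparison asked whether the long-day effect differed between vasculature and epidermis. It did for 3 of 18 wound and touch genes and 4 of 8 starvation genes, and the tests of both lists were lost with an estimated correlation (adjusted p = 0.145 and 0.0708). JAZ7 differed by 4.93 ± 0.532 (adjusted p = 0.000283), with 118 and 845 normalized counts in long-day and short-day epidermis and 426 and 87.7 in vasculature. DIN6 differed by 4.46 ± 0.662 (adjusted p = 0.00423), with 79.7, 3643, 540 and 933 in the same order. AT4G18440 differed by 4.34 ± 0.384 (adjusted p = 6.96e-05), with 265, 1478, 984 and 255. In the negative direction the chaperone gene HSP81-2 differed by −2.03 ± 0.329 (adjusted p = 0.00947), with 3442, 1425, 2046 and 3388.

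The effects differed for 102 genes, 93 toward vasculature and 9 toward epidermis, and for 1344 at an unadjusted p under 0.05. Of the 93, 58 fell in epidermis and were not called in vasculature, 16 fell in epidermis and rose in vasculature, and 16 were called in vasculature alone, where they rose. Wound and touch genes had 3 of 18 called, JAZ7, JAZ5 (3.13 ± 0.668) and ERF1A (1.88 ± 0.334), and 14 when adjusted over the list alone. Their camera adjusted p was 3.06e-14 (median 1.60), and 0.145 with an estimated correlation. Starvation genes had 4 of 8 called, DIN6, TPS8 (2.64 ± 0.343) and TPS11 (2.38 ± 0.354) among them, and 6 when adjusted over the list alone, with a camera adjusted p of 7.08e-11 (0.0708 with an estimated correlation). STP1 (3.06 ± 0.569), TT19 (1.71 ± 0.358), TPS5 (−2.00 ± 0.371) and RVE2 (−1.69 ± 0.301) were the members called in the starch, flavonoid and clock lists. The flavonoid list had a median of −0.38 and a mean of 0.175 and did not pass the camera test. Salicylic acid (median 1.23, adjusted p = 0.00195, and 0.202 with an estimated correlation), epidermis (median −0.35, 0.00195, and 0.538) and glucosinolate genes (median 0.50, 0.0108, and 0.553) passed at the preset correlation with 0 members called. The other lists, phloem (adjusted p = 0.0501) included, had 0 members called and did not pass.

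The largest differences, without overlap between photoperiods in at least 1 cell type, also included XTH18 (6.72 ± 1.17), PHI-1 (6.03 ± 1.3), AT3G29000 (4.07) and the jasmonate genes AOC3 (3.92) and ILL6 (3.87 ± 0.428). Chance meets this rule in more genes than in either cell type alone (10% in epidermis and 20% in vasculature). In the negative direction they included Hop3 (−2.48), ROF1 (−1.96), HSP81-3 (−1.91), iqd21 (−1.57) and Hsp70-15 (−1.55). CO, SUC2, FDH, ATML1, GI, FKF1, CCA1, LHY, TOC1, SOC1, RBCS1A, CA1, RANGAP1 and ACT2 were not called, with GI at 1.22 (adjusted p = 0.634) and FKF1 at −0.98 (adjusted p = 0.498). Of the 22 named calls, TPS8, JAZ7, AT4G18440 and ILL6 held without any 1 library. The other 18 did not, and 17 were lost without replicate 2 of short-day vasculature. Called genes numbered 518 without replicate 2 of short-day epidermis, 61 and 56 without its replicates 1 and 3, and 55, 37 and 58 without replicates 1, 2 and 3 of long-day epidermis. It was 42, 39 and 50 without those of long-day vasculature, and 27 and 11 without those of short-day vasculature.

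Accessibility was compared between the cell types in the same way (4 against 4 libraries). The largest decrease in vasculature was a peak at FDH, on chromosome 2 from 11173020 to 11174173, at −2.88 ± 0.0787 (adjusted p = 2.99e-18). It had 285 ± 0.797 CPM in long-day epidermis and 39.9 ± 1.93 in long-day vasculature (SD, n = 2). The largest increase overlapped EIL1, on chromosome 2 from 11548050 to 11548960, at 3.62 ± 0.145 (adjusted p = 8.88e-15), with 5.58 and 92.8. A peak at RANGAP1, on chromosome 3 from 23325037 to 23325478, was lower by −0.97 ± 0.140 (adjusted p = 0.000435). The FDH promoter is part of the transgene of the epidermis line, and the epidermis libraries had 0 reads over 1700 bp from 11548701 to 11550400, within and beside the EIL1 peak.

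**Figure D3:**
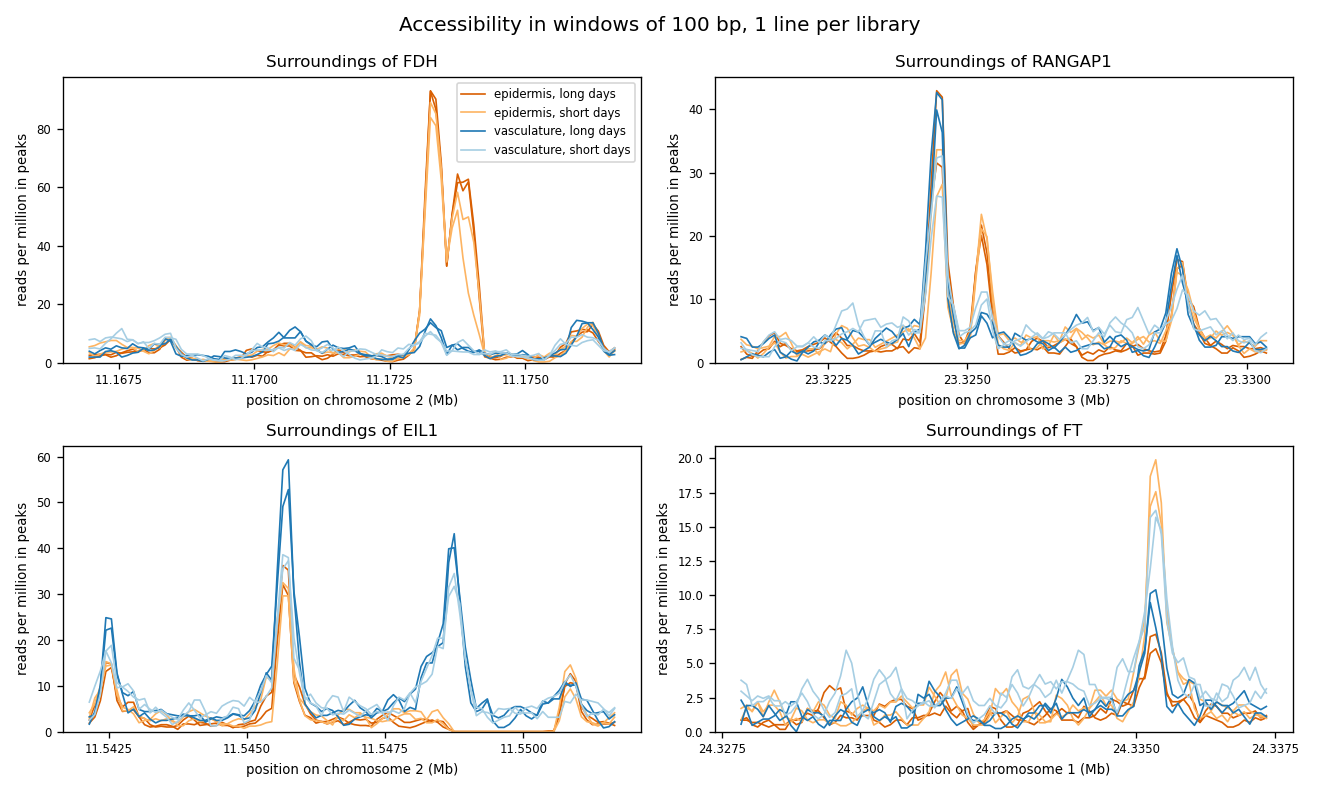
ATAC CPM, scaled to reads in peaks, in windows of 100 bp around FDH, RANGAP1, EIL1 and FT, 1 line per library. The epidermis lines lay above the vascular ones at the FDH peak and at 0 beside the EIL1 peak, and the short-day lines lay above the long-day ones at the peak beside FT.

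Of 34279 peaks tested, 216 differed between the cell types, 103 higher and 113 lower in vasculature, and 4458 had an unadjusted p under 0.05. Scaled to library totals alone, 143 were higher and 8488 lower. Of the called peaks 48.1% overlapped genes, against 63.5% of the tested ones. A change of at least 2-fold was seen in 39 (37 higher). They included peaks near AT3G29130 (chromosome 3, 11097193 to 11097539), at NS2 (chromosome 3, 2375602 to 2376100) and near AT2G28755 (chromosome 2, 12333821 to 12334002), which were higher by 2.17 ± 0.158 to 1.63. A peak near AT3G41762 (chromosome 3, 14199906 to 14200171) was lower by −1.42 ± 0.114, and 2 near AT1G62330 by −0.87 and −0.78. In the locus windows a peak 235 bp beside bZIP3, near CO, was 0.80 higher (adjusted p = 0.0434). The peaks near SUC2, ATML1, GI, SOC1, RBCS1A, ACT2 and FT were not called, with SUC2 at 0.14 (adjusted p = 0.74). Of the 11 named calls, 8 held without any 1 library, and those near bZIP3 and AT1G62330 (3 peaks) were lost without replicate 2 of short-day vasculature. The number of called peaks was 719 and 1639 without replicates 1 and 2 of short-day epidermis, 65 and 47 without those of long-day epidermis, 43 and 52 without those of long-day vasculature, and 61 and 41 without those of short-day vasculature.

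In epidermis (2 against 2 libraries) the question was which regions change with 3 long days. Of 31 peaks linked to photoperiod and flowering genes, 1 rose, 2 fell and 28 were not called. A peak 1179 bp beside FT (chromosome 1, 24335179 to 24335499) fell by 1.42 ± 0.203 (adjusted p = 2.79e-05), from 28.1 to 10.5 CPM, while FT RNA was read in long days alone. A peak at GI (chromosome 1, 8066967 to 8067965) fell by 1.87 ± 0.156 (adjusted p = 6.68e-09), from 81.2 to 22.2. A peak 468 bp beside SOC1 (chromosome 2, 18811594 to 18812181) fell by 0.52 ± 0.128 (adjusted p = 0.00739), while the peak linked to SOC1 by its reads, which overlaps the neighbouring AGL6, was not called (0.39, adjusted p = 0.0559). The largest fall within a gene was at AT1G73480 (chromosome 1, 27631900 to 27633194), by 2.94 ± 0.125 (adjusted p = 1.03e-13), from 159 to 20.8. A peak at AT5G58120 (chromosome 5, 23520344 to 23520890) rose by 2.31 ± 0.172 (adjusted p = 1.04e-09), from 15.4 to 75.9.

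Long days changed 4059 of 34279 peaks in epidermis, 1905 higher and 2154 lower, and 1237 at least 2-fold (433 higher and 804 lower). Scaled to library totals alone, 5298 were higher and 1300 lower. A peak near SUC2 (chromosome 1, 8033012 to 8033512) rose by 0.66 ± 0.212 (adjusted p = 0.0413). The largest rises also included peaks near AT4G30470 (2.62), AT1G56660 (2.41) and WRR4 (2.27), and the largest falls peaks at GRP7 (−2.88), SCRL22 (−2.78) and MEE14 (−2.77) and a peak 3079 bp beside AT3G47610 (−3.19). With 2 against 2 libraries, chance parts the groups in 33.3% of peaks. Peaks linked to the gene lists were counted after the values had been seen. Of 22 peaks linked to mesophyll genes, 12 were lower and 0 higher, such as those of LHCB2.2 (−1.47) and LHCB1.3 (−1.13). Of 18 wound genes, 5 had a higher one, such as WRKY33 (1.1), and 6 a lower one. Of 7 starvation genes 5 had a lower one, such as DIN6 (−1.39). Of 13 flavonoid genes 1 had a higher and 1 a lower one, although 12 rose in RNA, and of 27 epidermis genes 0 had a higher and 2 a lower one, although 6 rose in RNA. Of 30 clock genes 1 had a higher one (RVE2, 0.77) and 3 a lower one, PRR5 (−0.79) among them. Of the 16 named calls 12 held without any 1 library, and those near SUC2, PAB3, SOC1 and 1 of 2 near GI were lost without replicate 1 of long-day epidermis. Called peaks numbered 1936 and 1918 without replicates 1 and 2 of long-day epidermis.

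In vasculature (2 against 2 libraries) the same peak at GI fell by 2.17 ± 0.163 (adjusted p = 1.26e-09), from 100.2 to 22.3 CPM, and the peak beside FT by 0.81 ± 0.208 (adjusted p = 0.0102), from 25.1 to 14.3. The FT peak was not called without replicate 2 of long-day vasculature or either library of short-day vasculature. The peak at AT1G73480 fell by 3.06 ± 0.131 (adjusted p = 1.41e-13), from 173 to 20.9. A peak at SEX1, a starch degradation gene (chromosome 1, 3580527 to 3582075), fell by 2.67 ± 0.150 (adjusted p = 8.58e-12), from 112 to 17.5. Peaks near RBCS1A rose, the largest (chromosome 1, 25047355 to 25048149) by 0.89 ± 0.108 (adjusted p = 3.12e-06), from 73.6 to 137.

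Long days changed 4727 of 34279 peaks in vasculature, 2267 higher and 2460 lower, and 1264 at least 2-fold (253 higher and 1011 lower). Scaled to library totals alone, 10041 were higher and 1119 lower. The largest rises were near MYB28 (chromosome 5, 24688727 to 24688842, 2.23 ± 0.359), MBD12 (2.02), AT4G19420 (1.84), AT5G22920 (1.81) and AT3G24880 (1.80), and further falls were near AT2G34930 (−2.70) and FAMT (−2.52). In the locus windows a peak near ACT2 rose by 0.46 ± 0.0951, and the peak near SUC2 (0.56, adjusted p = 0.0841) was not called. Among linked peaks, counted after the values had been seen, 14 of 18 wound genes had a lower one and 0 a higher one, such as LOX3 (−1.65) and JAZ7 (−1.60). Of 13 flavonoid genes 6 had a higher one and 0 a lower one, and of 27 epidermis genes 6 had a higher one, such as KCS6 (1.04). Of 22 peaks linked to mesophyll genes 5 were higher and 2 lower, of 7 linked to starvation genes 2 and 2, and of 30 linked to clock genes 3 and 1. Of the 20 named calls 11 held without any 1 library, and 9, those near FT, ACT2, AT5G22920 and AT3G24880 and 1 each near GI and RBCS1A among them, were lost without replicate 2 of short-day vasculature. The number of called peaks was 2160 and 1945 without replicates 1 and 2 of long-day vasculature, and 2474 and 1779 without those of short-day vasculature. In both cell types 1601 peaks were called, 1278 in the same direction (479 higher and 799 lower, against 126 and 155 by independent lists) and 323 in opposite directions.

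The last accessibility comparison asked whether the long-day effect differed between the cell types. A peak at the immune receptor gene WRR4 (chromosome 1, 21171140 to 21171583) differed by −3.05 ± 0.254 (adjusted p = 6.44e-09), with 52.5 and 16.0 CPM in long-day and short-day epidermis and 18.6 and 47.5 in vasculature. A peak at PORB, a chlorophyll synthesis gene (chromosome 4, 13727159 to 13727613), differed by 1.99 ± 0.266 (adjusted p = 1.75e-05), with 14.4, 26.1, 33.8 and 15.3 in the same order. Near RBCS1A 2 peaks differed by 0.96 ± 0.149 and 0.69. In contrast to its RNA, JAZ7 had a linked peak that fell in both cell types (−0.72 in epidermis and −1.60 in vasculature).

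The effects differed at 1695 of 34279 peaks, 564 toward vasculature and 1131 toward epidermis, and 922 by at least 2-fold (174 and 748). Scaled to library totals alone, 1302 differed toward vasculature and 865 toward epidermis. Of the 1131, 298 rose in epidermis and fell in vasculature, 422 fell in vasculature alone and 320 rose in epidermis alone. Of the 564, 271 rose in vasculature alone and 205 fell in epidermis alone. Of the called peaks 80.1% overlapped genes. The largest differences were near MEE14 (2.57), AT5G25280 (2.24), TIP2 (2.06) and CCL (2.01) toward vasculature, and at a second peak of WRR4 (−3.24), at AT5G58120 (−3.23), AT3G27210 (−3.19) and AT4G19520 (−3.06) toward epidermis. Chance meets their rule of no overlap in at least 1 cell type in more than the 33.3% of peaks for 1 cell type. Among linked peaks, 8 of 18 wound genes differed toward epidermis and 0 toward vasculature, such as LOX3 (−1.90), WRKY33 (−1.91), WRKY40 (−1.51) and TCH3 (−1.21). Of 7 starvation genes 3 differed toward vasculature and 0 toward epidermis, such as DIN6 (0.60). Of 22 peaks linked to mesophyll genes 9 differed toward vasculature and 0 toward epidermis, such as those of LHCB1.3 (1.24) and LHCB2.2 (0.96). Of the 12 named calls 11 held without any 1 library, and 1 of the RBCS1A peaks was lost without replicate 2 of long-day epidermis. Called peaks numbered 1041 and 904 without replicates 1 and 2 of long-day epidermis, 2581 and 3325 without those of short-day epidermis, 876 and 855 without those of long-day vasculature, and 1020 and 825 without those of short-day vasculature.

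The authors' peak lists held 31300 peaks in long-day epidermis, 28764 in short-day epidermis, 28313 in long-day vasculature and 26898 in short-day vasculature. Their median fold over the local background was 3.56, 3.48, 3.56 and 2.98. Of the short-day peaks 90.6% in epidermis and 85.6% in vasculature overlapped a long-day peak of the same cell type. Of the vascular peaks 93.4% in long days and 88.7% in short days overlapped an epidermal peak of the same photoperiod. The reverse shares were lower. Of the long-day peaks 78.8% in epidermis and 78.5% in vasculature overlapped a short-day peak of the same cell type. Of the epidermal peaks 79.4% in long days and 79.6% in short days overlapped a vascular peak of the same photoperiod. Merged, the lists gave 34684 regions with a median width of 247 bp, of which 18896 (54.5%) were in all 4 lists. Both epidermis lists and no vascular list held 1159 regions, and both vascular lists and no epidermis list held 147. Each list came from 1 pool of 2 libraries of different depth, so the counts carry no error.

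Peaks within 1000 bp of a gene were set against its nuclear RNA for 14088 genes. In epidermis 483 of 1579 genes with changed RNA had a changed peak (30.6%), 412 of them in the same direction (85.3%, two-sided Fisher exact p = 2.41e-61), such as DIN6, LHCB2.2 and RVE2. In the others the peak rose and the RNA fell at 60 genes, and the peak fell and the RNA rose at 11. In vasculature 357 of 1072 genes had a changed peak (33.3%), 296 in the same direction (82.9%, p = 4.90e-38 by Fisher's exact test), such as RVE2, PIF4 and PRR5. Both tests count genes as independent replicates, which they are not, and 1 peak can stand for several genes. Their p values are therefore likely too small. The linked peak of GI, the one with the most reads, was not called in epidermis (−0.18, adjusted p = 0.172) or vasculature (0.017, adjusted p = 0.925). Of the 99 genes whose long-day effect on RNA differed between the cell types, 25 had a peak that differed, 7 in the same direction and 18 with accessibility toward epidermis and RNA toward vasculature (Fisher's exact p = 1). Only 1 of the 25 had RNA toward epidermis, too few for this test to reach a p under 0.05, so it decides nothing here. Of 106 genes whose RNA differed between the cell types, 2 had a peak that did. Across genes, which are not independent replicates, Spearman's rho was 0.200 in epidermis, 0.151 in vasculature, −0.118 for the difference of the effects and 0.0154 between the cell types.

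**Figure D4:**
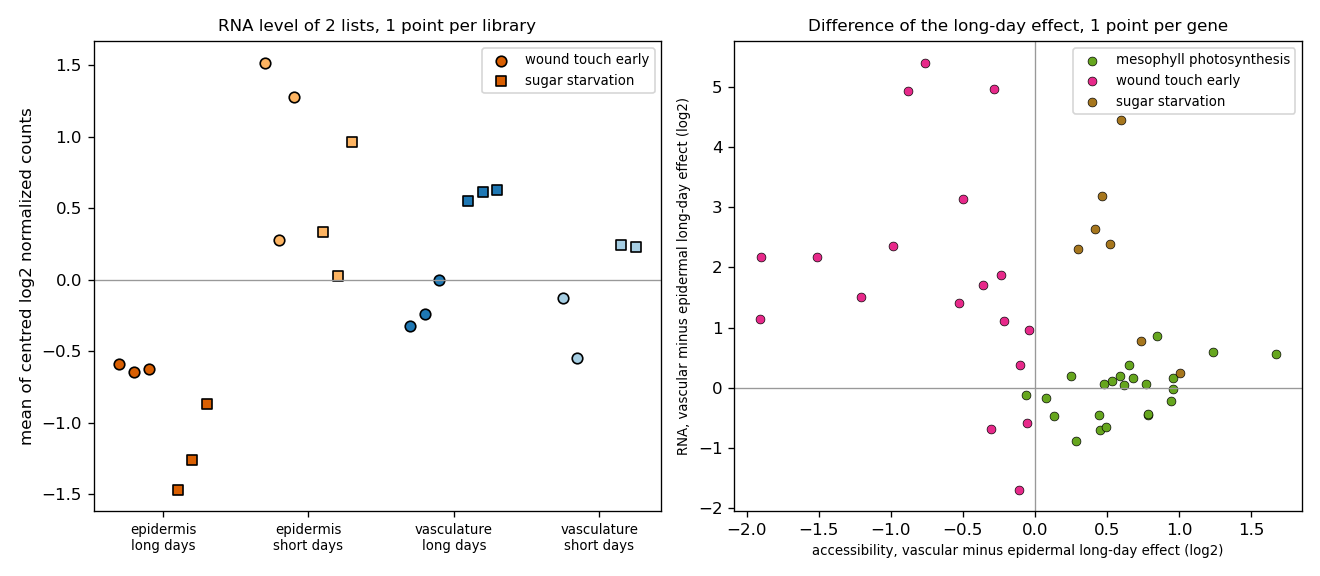
Mean centred log2 level of the wound and starvation lists in each RNA library (left), and the difference of the long-day effect between vasculature and epidermis in RNA against accessibility, 1 point per gene (right). In short-day epidermis the wound list lay at 1.52, 0.28 and 1.28 in the 3 libraries, and between −0.64 and 0.00 in all others.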

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

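The tests of explanations given here were chosen after the results had been seen. The results listed here stood out because the long-day effect differed between vasculature and epidermis in a test of that difference (limma for RNA, edgeR for accessibility, adjusted over all genes or peaks). It did for 102 genes and 1695 peaks. Among named genes the vascular minus epidermal effect (log2) was 6.72 for XTH18, 6.03 for PHI-1, 4.93 for JAZ7, 3.13 for JAZ5, 1.88 for ERF1A, 3.92 for AOC3, 3.87 for ILL6, 4.34 for AT4G18440 and 4.07 for AT3G29000. It was 4.46 for DIN6, 2.64 for TPS8, 2.38 for TPS11, 3.06 for STP1 and 1.71 for TT19. Negative values were −2.00 for TPS5, −1.69 for RVE2, −2.03 for HSP81-2, −1.91 for HSP81-3, −2.48 for Hop3, −1.96 for ROF1, −1.57 for iqd21 and −1.55 for Hsp70-15. Among peaks it was 0.96 and 0.69 at RBCS1A, 2.57 near MEE14, 2.24 near AT5G25280, 2.06 near TIP2, 2.01 near CCL and 1.99 at PORB. It was −3.24 and −3.05 at WRR4, −3.23 at AT5G58120, −3.19 at AT3G27210 and −3.06 at AT4G19520.

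Wound and touch RNA was high in short-day epidermis, while the starvation list stood apart by being low in long-day epidermis (−1.47, −1.26 and −0.87, against 0.33, 0.03 and 0.96 in short days). If handling differed between preparations, libraries of that group would differ among themselves, and their wound list levels did, over a range of 1.24 (1.52, 0.28 and 1.28) against at most 0.420 in another group, a range that rests on replicate 2 (0.28), whose identity is itself in doubt. Against low depth of the third libraries as the cause, the median difference of the wound list was 1.35 without the 3 shallow libraries and 1.60 with them. Handling may account for the wound list, but without replicate 2 the range gives no sign of it, while a response of the epidermis to short days, which was not tested apart from handling, also stays open.

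The lines differed in accessibility at FDH, RANGAP1 and EIL1. If gene segments in the transgene added copies, the difference would end at the segment. Reads inside the peak were 8.33 times as many in epidermis as in vasculature at FDH (0.783 in its flanks, a ratio of 10.6) and 2.25 times at RANGAP1 (0.822 in its flanks, a ratio of 2.74). Copies may therefore account for both, but an accessible region that is specific to epidermis would also end at its edges, and the tag with its RANGAP1 segment is in both lines, so this stays open. At EIL1 a segment missing from the epidermis line may account for part of the difference, since 17 consecutive windows of 100 bp had 0 reads in every epidermis library and reads in every vascular one, with 0 such windows in the other plotted regions; over the rest of the peak, from 11548101 to 11548700, epidermis libraries had reads (0.485 to 4.77 CPM per window) below the vascular ones (10.3 to 39.9), and what lowered these was not tested.

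The long-day effect on accessibility differed at 8 of 18 peaks linked to wound genes: 5 of them rose in epidermis and fell in vasculature (LOX3, ZAT10, WRKY33, WRKY40 and TCH3), while that of JAZ7 fell in both. The linked peaks had a median difference of −0.43, while the RNA of the list differed by 1.60, and handling that differed between the separate RNA and ATAC preparations may account for the opposite signs; peaks linked to the starvation list went the way of its RNA (medians of 0.52 and 2.34). Against different flow cells as the whole cause, the difference in libraries of the first flow cell was 1.01 times that in all libraries (partly built in, as 5 of the 8 libraries are on it), and with a flow cell term 852 peaks were called, 757 of them among the 1695. An unequal share of reads in peaks can give trends with peak abundance, and with a loess offset, which removes these, 92.4% (1566) of the 1695 stayed called. The offset does not test the scaling itself. Scaled to library totals, 2167 peaks were called, 1429 of them among the 1695. Of the 2167, 1302 differed toward vasculature and 865 toward epidermis, against 564 and 1131 in the main fit, so the balance of directions depends on the scaling. A real difference of the photoperiod response between the cell types stays open and was not tested apart from handling.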

How the results depend on the processing

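The alternatives with limma voom weights, without the 3 shallow libraries, with a flow cell term, with the first flow cell alone, with a mapping quality of at least 30 and with crossed pairing were chosen after seeing the data. The rest had been set before. Of the other settings of the 182 named RNA values, 2157 kept direction and side of the threshold, 82 lost the call, 17 gained one and 17 changed sign. Of those of the 59 named peaks, 761 kept both, 71 lost the call and 0 changed sign. Without 1 library, 1732 RNA values kept both, 228 lost the call, 5 gained one and 37 changed sign, and 416 peak values kept both and 56 lost the call. Where a group kept 1 library, it was assumed to vary like the other groups. Motif tests, and promoter and exon classes, were not run for lack of a genome sequence and of strands, and "only the 2 groups compared" applied to the long-day contrasts alone. At this depth FT was below the count filter, and its long-day level was set against a limit of 3 reads in short days. The causes of the changes below were not tested, apart from fewer libraries or a stricter threshold where the setting itself has these.

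The RNA difference between cell types (145 genes) came to 248 with quantile normalization (129 higher and 119 lower), 325 with edgeR (142 and 183), 573 with DESeq2 (242 and 331), 408 with voom weights (209 and 199) and 218 without the 3 shallow libraries (121 and 97). The long-day effect in epidermis (1650 genes) stayed within 1.5 times under every setting run. In vasculature (1125) it came to 1717 with DESeq2 and 1901 with voom weights. Fitted on only the 2 groups of a contrast, 1183 genes were called in epidermis and 1652 in vasculature. The order of the cell types by called genes was then reversed, so these counts do not show which cell type responds more. The difference of the effects (102) came to 226 with edgeR, 394 with DESeq2 and 34 without the 3 shallow libraries. Equal nuclear totals gave 1055 higher and 718 lower genes in epidermis and moved the median of all genes in epidermis from 0.0158 to 0.172 and in the difference from −0.05 to −0.14. With the replicate block the counts were 167, 1824, 1057 and 99 for RNA and 151, 3873, 4475 and 1565 for peaks. With an estimated correlation the gene lists past the camera test went from 8, 9, 5 and 5 to 0, 1, 1 and 0. With fry, which tests whether the genes of a list move one way and does not compare them with other genes, 7, 10, 6 and 3 passed.

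For peaks between cell types (216) library totals gave 8631 (143 higher and 8488 lower), a loess offset 123 (85 and 38), DESeq2 116 (28 and 88), stricter peaks 114 (72 and 42), identical positions counted once 77 (52 and 25), an absolute log2 of at least 1 39, a flow cell term 117 and the first flow cell alone 1323. In epidermis (4059) library totals gave 6598 (5298 and 1300), DESeq2 2221, stricter peaks 2564, only the 2 groups 2439, an absolute log2 of at least 1 1237 and the first flow cell alone 6584. In vasculature (4727) library totals gave 11160 (10041 and 1119), DESeq2 2686, stricter peaks 2869, only the 2 groups 6983, an absolute log2 of at least 1 1264 and a flow cell term 2484. For the difference (1695) library totals gave 2167 (1302 and 865), DESeq2 996, stricter peaks 1069, an absolute log2 of at least 1 922, a flow cell term 852 and the first flow cell alone 2987. Library totals moved the median of all peaks to −0.24 between cell types, 0.206 in epidermis, 0.331 in vasculature and 0.152 in the difference. With at least 50 percent of a peak shared, 90.2% of short-day peaks in epidermis and 85.1% in vasculature overlapped a long-day peak. Of the vascular peaks, 92.9% in long days and 88.2% in short days then overlapped an epidermal peak.

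Without 1 library, the RNA counts ranged from 15 to 567 between cell types, 1122 to 2091 in epidermis, 425 to 1391 in vasculature and 11 to 518 for the difference. The peak counts ranged from 41 to 1639, 1918 to 5843, 1779 to 6898 and 825 to 3325.

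No call changed sign. Uncalled values that did (log2) were, between cell types, ATML1 at 0.015 with equal nuclear totals and 0.069 with the replicate block, and ACT2 at 0.010, 0.033 and, without the 3 shallow libraries, 0.098. LHY was −0.027 with a pseudocount of 5 and −0.11 with quantile normalization, and RBCS1A 0.073 with the latter. In epidermis CCA1 was 0.030 with equal nuclear totals. In vasculature ATML1 was −0.11 with the block, −0.18 without the shallow libraries and −0.049 with voom weights, CA1 0.151 with quantile normalization and 0.040 with equal nuclear totals, and RANGAP1 −0.035 without the shallow libraries. TOC1 in the difference was −0.13 with quantile normalization and −0.020 with equal nuclear totals.

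Without 1 library, values that changed sign ranged, between cell types, from −0.16 to 0.057 for ACT2, −0.19 to 0.087 for ATML1, −0.15 to 0.28 for CO and −0.33 to 0.88 for LHY. In epidermis CCA1 ranged from −0.37 to 0.14. In vasculature the ranges were −0.18 to 0.27 for ATML1, −0.16 to 0.10 for CA1, −0.36 to 0.82 for CCA1, −0.37 to 0.49 for CO and −0.22 to 0.38 for RANGAP1. In the difference they were −0.23 to 0.94 for CCA1, −0.81 to 0.055 for CO, −0.27 to 0.13 for RBCS1A and −0.086 to 0.23 for TOC1.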

Other observations

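The genes and tests named here were chosen after the values had been seen, except for the test on 171 genes. Accessibility and RNA moved together in both cell types at several genes. Long days raised the linked peak and the RNA of the clock gene RVE2 (peak 0.77 in epidermis and 1.26 in vasculature), of the anthocyanin regulator PAP2 (1.69 and 1.15), of the starch degradation gene BAM3 (0.68 and 0.62) and of the defence regulator WRKY70 (0.83 and 0.79). The RNA calls of WRKY70 in both cell types and of PAP2 in vasculature were lost without some single libraries. Long days lowered both for PIF4 (−0.94 and −0.53). At the cyclin gene CYCD3;1 the linked peak rose by 1.12 in epidermis and fell by 0.94 in vasculature, a difference of −2.06.

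The phloem list lay at 0.84, 0.77 and 0.66 (mean centred log2) in the libraries of long-day vasculature and at 0.37 and 0.47 in short-day vasculature. It lay at 0.13, −0.13 and −0.03 in long-day epidermis, and at −0.45, −0.74 and −1.90 in short-day epidermis. The starvation list was lowest in long-day epidermis (−1.47, −1.26 and −0.87). Accessibility in the 2 libraries of short-day epidermis correlated at 0.946, against 0.965 to 0.975 in the other groups. Replicate 2 correlated slightly better with replicate 2 of short-day vasculature (0.947) than with replicate 1 of its own group. It was the only ATAC library nearer to another group, and was sequenced on another flow cell than replicate 1. Why it lay there was not tested.

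Replicate 2 of short-day epidermis had the lowest wound level of its group. The mean correlation of its RNA with its own group was 0.899 and the best with another group 0.943. Its best with a library of its own group was 0.908. The second libraries of long-day epidermis (0.938 and 0.941) and long-day vasculature (0.916 and 0.937) also had a best value with another group above their own mean. So had the first of long-day vasculature (0.913 and 0.941). Their best with a library of their own group was higher, however (0.956 in long-day epidermis, 0.952 in long-day vasculature). Replicate 2 of short-day epidermis was thus the only RNA library whose best correlation was with another group. That it is a mislabelled vascular library was tested in 4 ways, which pointed in different directions. Of the 171 genes that separated the cell types in long days alone, it lay nearer its own group in 45.0%, under the bound of 50 percent set beforehand for a mislabelled library, against 69.6% and 66.7% for replicates 1 and 3. Of the 567 genes called without it, it lay nearer its own group in 35.3%, against 95.2% and 92.8% for the others, which had helped to select those genes. The markers of the transgenic lines, looked at afterwards, pointed the other way. RANGAP1 had 392 normalized counts in it, above the highest vascular library (184), and EIL1 had 146, below the lowest vascular library (578), as in the other epidermis libraries. A library of the vascular line is hard to reconcile with these levels, while nuclei of the epidermis line with RNA closer to vasculature may explain both kinds of test, and this stays open.

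Groupings of the same libraries other than the real one were also fitted. For RNA between cell types the real grouping called 105 genes in a fit without the interaction and the others 11 at most. It was thus the 1 of 100 that called as many, the smallest share that 100 groupings can give. Chance is unlikely to give this but is not excluded, and the test does not part cell type from transgenic line. For RNA in epidermis the real grouping called 1191 genes and the others 0, and 10 groupings are too few for a share under 0.05. For peaks between cell types 2 of 34 groupings called at least the 31 peaks of the real one, itself included. The other called 1119 peaks and set long-day epidermis with short-day vasculature against the rest, which is the structure of the difference between the long-day effects, so this count does not tell whether chance can be excluded.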
